A study of Mus musculus with 6 samples.

How the data were processed

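RNA was measured in 6 pools of proprioceptive sensory neurons of the mouse, 3 supplying the tibialis anterior muscle (TA) and 3 supplying the gastrocnemius muscle (GS). Per the series' design text, a tracer was injected into 1 of the muscles at postnatal day 0 in a reporter line that marks parvalbumin neurons, and labelled neurons were picked by hand at postnatal day 1. Each pool held 25 to 30 neurons. Per the labels' protocols, RNA was extracted with the PicoPure kit, amplified into cDNA with the Nugen Ovation RNA-Seq System, and made into libraries with the Nextera kit. Paired-end sequencing on an Illumina HiSeq was stated as 25000000 to 30000000 reads per sample. Whether the counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart. The submitters' processing notes name Bowtie 0.12.9, DESeq with no version, and the mouse genome build mm9. The program that assigned reads to genes and its annotation release are not given in the sources used here.

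The deposited whole-series table lists 36814 genes with a whole number of reads and an RPKM value per library, per the file headers. In 683 genes at least 1 library had a value below 0. How such values arose is not given in the sources used here, and all are called net reads and net RPKM. Within each library the deposited RPKM values equalled the net reads divided by gene length and by 1 constant total. That total ranged from 13167570 in TA replicate 2 to 32977601 in TA replicate 3. All 38 genes of the mitochondrial chromosome were listed at 0 in every library, so a 0 in this table is described only as listed at 0. The authors also deposited a list of genes higher in TA and a list of genes higher in GS. Each gives a scaled read signal per muscle, the ratio (fold) of GS over TA, a p-value, an adjusted p-value and an RPKM per muscle, per the file headers. In these lists the authors' signal for TA was 0.842 times the sum of the 3 TA libraries' net reads, and that for GS was 1.19 times the sum of the 3 GS libraries. The largest deviation from these factors was 0.0469% over 503 TA list and GS list genes with a TA signal above 100, and 0.0453% over 388 with a GS signal above 100. The signals were therefore 1 summed value per muscle, and how the deposited p-values were computed from them is not given in the sources used here. Every listed gene had a deposited p-value of at most 0.0499 and a ratio of at least 5 in its direction.

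The design, fixed before the values were seen, took the table as RPKM and allowed a count model only for plain counts. The read columns held values below 0, so the comparison was made on RPKM. Genes with any value below 0 were left out, which removed 43 genes with a mean RPKM of at least 1. One entry per gene symbol was kept, the one with the highest mean, and genes entered with a mean RPKM of at least 1 over the 6 libraries, leaving 10828. TA and GS were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with group as the only term, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Log2 fold changes are TA minus GS on the log2(RPKM + 1) scale, which understates the change of genes with low values. Folds are ratios of mean RPKM. Fixed gene lists, 22 in all, were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Members were also counted as called over all genes and as adjusted over the list alone. Library similarity was described by Pearson correlation across genes and by principal components.

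The design, the gene lists and the rule for named genes were set before the data were examined. In each direction the rule took the 10 called genes with the largest log2 fold change whose TA and GS values did not overlap. It added every measured member of the muscle-type list. From each other list it took members past the threshold, or else the 3 with the smallest unadjusted p. From lists of cell identity, other cell types and sex it also took the 4 members with the highest mean. Gene models with no official symbol were counted and not named. Gene symbols are those of the deposited table, and 31841 of its identifiers matched the reference name table. Coordinates are those of the deposited table in mm9, with the end given as the last base. The table's end lay 1 base beyond the end in the deposited lists for all 728 genes compared.

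The steps were tested on simulated data built from the 10828 genes, with 100 genes changed at each fold. The fit recovered 57% of genes changed 4-fold and 85% of genes changed 8-fold, with 0 in the wrong direction, a mean of 7.4 false calls and 0 lists called over 5 simulations. Each simulated gene had the median spread of genes of like mean. No simulated library stood apart and no shift towards TA was built in, so these rates need not hold for the real libraries. The changed genes were drawn at random and balanced in direction, so the 0 lists called does not measure power for lists. Alternatives changed the pseudocount to 0.1 or 5, the filter, the scaling, the variance model, the sample weights, the threshold, the set test and the replicate block, and left out each replicate in turn. Added after seeing the data were values below 0 set to 0, limma voom on net reads, leaving out GS replicate 2 and TA replicate 3 together, and a variance trend in camera. The reads carry no molecular identifiers, so read numbers are not numbers of RNA molecules.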

Results

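Proprioceptive sensory neurons report muscle length and force to the spinal cord. The transcriptomes of proprioceptors supplying TA, which flexes the ankle, were set against those of proprioceptors supplying GS, which extends it, with 3 pools per muscle labelled as biological replicates. Whether the pools came from different animals is not given in the sources used here. Net reads assigned to genes came to 8348117, 12226365 and 8754342 in GS replicates 1, 2 and 3, and to 9207075, 7038296 and 21125960 in TA replicates 1, 2 and 3. Genes with at least 1 net read numbered 13950, 12658 and 15432 in the GS libraries and 16302, 15530 and 15966 in the TA libraries.

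All 6 libraries held high levels of large sensory neuron transcripts. The neurofilament genes Nefl and Nefm had mean values of 4442 ± 514 and 2615 ± 319 RPKM in TA and 4321 ± 476 and 2839 ± 1525 RPKM in GS (SD, n = 3). Etv1, a transcription factor of proprioceptors, was at 227 ± 32.1 RPKM in TA and 319 ± 5.59 RPKM in GS, an adjusted p of 0.524. Nefh was at 277 ± 7.68 RPKM in TA and 287 ± 26.9 RPKM in GS, and did not pass the test. Nefl and Nefm overlap in the annotation, and how reads in the overlap were assigned is not given in the sources used here.

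Libraries of the same muscle were not uniformly more alike than libraries of different muscles. The mean correlation across genes was 0.875 ± 0.0264 (SD, 3 pairs) within TA, 0.761 ± 0.0492 (3 pairs) within GS and 0.790 ± 0.0586 (9 pairs) between muscles, where pairs share libraries. TA replicates 1 and 2 had the highest value, 0.905. GS replicate 2 had the lowest mean correlation with the other 5 libraries, 0.728, against 0.780 to 0.834 for the others. The first principal component, 39.2% of the variance, set GS replicate 2 apart, and the second, 26.2%, set GS replicate 1 apart.

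**Figure D1:**
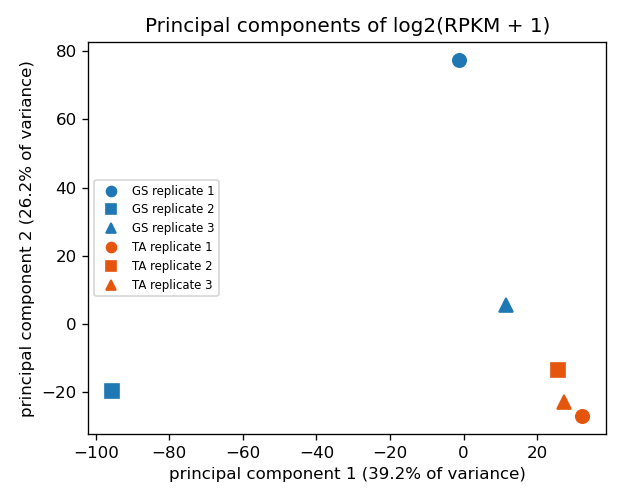
Principal components 1 and 2 of log2(RPKM + 1) over 10828 genes, in arbitrary units, with 1 point per library, coloured by muscle. GS replicate 2 sits at -95.6 on the first axis and the other 5 libraries between -1.20 and 32.3.

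The first comparison asked which genes distinguish proprioceptors by the muscle they supply. TA proprioceptors had more transcript of Vstm2b, an immunoglobulin domain protein, at 93.5 ± 19.4 RPKM in TA and 3.90 ± 2.30 RPKM in GS (SD, n = 3), a 24.0-fold difference. They also had more Sema5a, a transmembrane semaphorin, at 56.6 ± 4.98 against 6.98 ± 5.54 RPKM. GS proprioceptors had more Alcam, a cell adhesion molecule of the immunoglobulin family, at 174 ± 54.2 RPKM against 10.4 ± 3.23 RPKM in TA, a 16.7-fold difference. They also had more Rgs4, a regulator of G protein signalling, at 100.2 ± 35.0 against 3.88 ± 2.89 RPKM, a 25.8-fold difference. In all 4 genes the 3 TA values and the 3 GS values did not overlap.

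Of 10828 genes tested with limma, 19 were higher in TA and 14 higher in GS at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1129 genes, 899 higher in TA and 230 higher in GS. The TA and GS values did not overlap in any of the 33 called genes. Over all genes tested 16.6% did not overlap, 1422 towards TA (13.1%) and 377 towards GS (3.48%), where chance gives 10% for 3 against 3 in both directions together. At a common read depth, reached by a random draw of reads, each GS library held fewer detected features than each TA library. The gap was small between GS replicate 3 (15156) and TA replicate 3 (15215). The imbalance towards TA cannot be told apart from that difference in detection. The median log2 fold change of all genes was 0.24 towards TA. Values relative to that shift were 4.12 for Vstm2b, 2.83 for Sema5a, -4.16 for Alcam and -4.75 for Rgs4. Centring each library on its median gave 11 genes higher in TA and 17 higher in GS, and quantile normalization gave 16 and 19. At an unadjusted p under 0.05 these gave 508 and 411, and 492 and 444. All 33 genes kept their direction under both.

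Among the genes higher in TA, Vstm2b (ENSMUSG00000039257, chromosome 7, 48154648 to 48185338, plus strand, mm9) had a log2 fold change of 4.36 ± 0.42 (SE) and an adjusted p of 0.00347. Smyd1, a histone methyltransferase known from striated muscle, was at 32.9 ± 3.24 RPKM in TA and 1.72 ± 2.23 RPKM in GS, a log2 fold change of 3.97 ± 0.56 and an adjusted p of 0.0203. Syt17, of the synaptotagmin family, was at 13.9 ± 1.61 RPKM in TA and rested on 4 net reads in the GS libraries together, with an adjusted p of 0.00682. Amigo2, a leucine-rich repeat adhesion protein, had a log2 fold change of 3.44 and an adjusted p of 0.0150. Oxtr, the oxytocin receptor, was at 13.4 ± 6.95 RPKM in TA and 0.346 ± 0.198 RPKM in GS, with an adjusted p of 0.0203. Rgma, a repulsive guidance molecule that also binds bone morphogenetic proteins, was at 26.9 ± 14.3 against 2.25 ± 1.34 RPKM, with an adjusted p of 0.0304. Gucy1a3, a subunit of soluble guanylate cyclase now named Gucy1a1, had a log2 fold change of 3.04 and an adjusted p of 0.0203. Fxyd6, a regulator of the sodium pump, was at 6.82 ± 1.19 RPKM in TA, was listed at 0 in all 3 GS libraries and had an adjusted p of 0.0239. Crisp1 had a log2 fold change of 3.42 and an adjusted p of 0.0150. Crisp1 overlaps the related gene Crisp3, so its reads are uncertain, and Amigo2 and Rgma each overlap another annotated gene.

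Among the genes higher in GS, Alcam (chromosome 16, 52249109 to 52454187, minus strand, mm9) had a log2 fold change of -3.93 ± 0.37 and an adjusted p of 0.00347. Rgs4 (chromosome 1, 171671608 to 171677773, minus strand) had -4.52 ± 0.51 and an adjusted p of 0.00682. Crtac1, a secreted cartilage acidic protein, was at 25.8 ± 9.56 RPKM in GS and 1.03 ± 0.259 RPKM in TA, with an adjusted p of 0.00682. Spp1, the secreted phosphoprotein osteopontin, was at 56.5 ± 16.9 against 5.36 ± 2.25 RPKM, with an adjusted p of 0.0150. Klf3, a zinc finger repressor, was at 14.9 ± 8.80 against 0.200 ± 0.264 RPKM, with an adjusted p of 0.0203. Stc1, the secreted hormone stanniocalcin, had a log2 fold change of -3.25 and an adjusted p of 0.0203. Mme, the membrane peptidase neprilysin, had -3.58 and an adjusted p of 0.0213. Doc2b, a calcium sensor of vesicle release, had -3.11 and an adjusted p of 0.0208, and overlaps another annotated gene. Cdh20, a cadherin, was at 10.2 ± 4.45 against 0.417 ± 0.374 RPKM, with an adjusted p of 0.0370, and overlaps 3 other annotated genes. Cacng5, an auxiliary subunit of AMPA receptors, had -2.78 and an adjusted p of 0.0478.

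**Figure D2:**
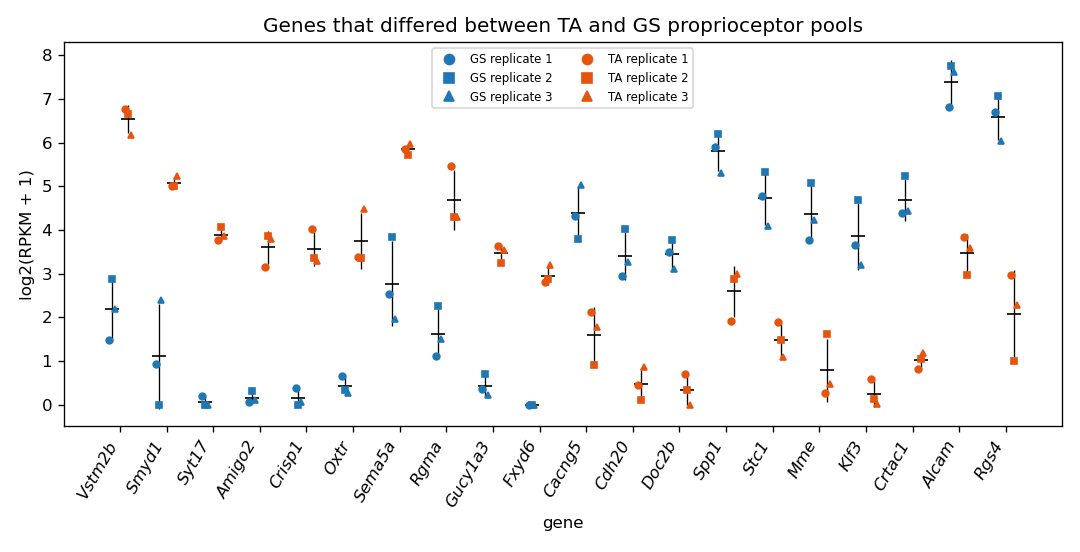
log2(RPKM + 1) of the 20 genes named by size of change, 10 per direction, in each library. Points are single libraries, bars are the mean and SD of 3 libraries, and the TA and GS points of each gene do not overlap.

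The counts moved when single libraries were left out. Leaving out 1 TA replicate left 1 gene higher in TA, Vstm2b, and 2 higher in GS without TA replicate 1 or 2 (Alcam and Rgs4) or 1 without TA replicate 3 (Alcam). Without GS replicate 1 there were 3 and 3, without GS replicate 2 there were 19 and 10, and without GS replicate 3 there were 16 and 7.

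Genes of the muscle-type list, described for proprioceptors of different limb muscles, were counted next. Of its 9 members, 6 passed the filter. Vstm2b and Sema5a were higher in TA, Crtac1 was higher in GS, and the other 3 did not pass the test over all genes. Cdh13, T-cadherin, was at 17.7 ± 3.47 RPKM in TA and 1.52 ± 2.30 RPKM in GS, with an adjusted p of 0.0619. Gabrg1, a GABA-A receptor subunit, was at 12.2 ± 3.75 against 22.0 ± 1.90 RPKM, and Efna5, an ephrin, at 10.9 ± 0.758 against 8.40 ± 5.31 RPKM. Adjusted over the list alone, 3 were higher in TA and 2 higher in GS. The list may have been chosen partly on these samples, so its counts are not independent evidence. Its members go both ways, with a median of 1.57 relative to all genes and a camera adjusted p of 0.361. Tox, Epha3 and C1ql2 lay below the filter.

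Genes of axon guidance and cell adhesion formed 4 lists. Among 21 semaphorins, plexins and neuropilins tested, 1 was called, Sema5a, higher in TA, and 5 were higher in TA and 1 in GS adjusted over the list alone (camera adjusted p of 0.521). Among 22 cadherins and protocadherins, 1 was called, Cdh20, higher in GS. Adjusted over the list alone, 3 were higher in TA and 5 in GS. This list's camera adjusted p was 0.0558 towards GS, and 0.684 with an estimated correlation, and its median was -0.23 relative to all genes. None of 8 Eph receptors and ephrins was called, and Epha6, an Eph receptor, was at 7.86 ± 1.70 RPKM in TA and 1.33 ± 0.828 RPKM in GS, the only member past the threshold when adjusted over the list alone (camera adjusted p of 0.944). None of 18 Slit, Robo, netrin and Unc5 genes was called, also when adjusted over the list alone (camera adjusted p of 0.517). Unc5a, a netrin receptor, was at 5.38 ± 2.25 against 0.861 ± 1.36 RPKM.

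None of the 14 Hox genes of paralog groups 4 to 13 was called over all genes or adjusted over the list alone. Their median log2 fold change was -0.47 relative to all genes, and the camera adjusted p was 0.0558 towards GS, or 0.684 with an estimated correlation. Hoxa5 was at 2.83 ± 1.37 RPKM in GS and 0.690 ± 0.213 RPKM in TA, and Hoxb9 at 14.8 ± 2.17 against 9.67 ± 4.12 RPKM. Without GS replicates 1, 2 and 3 in turn the Hox list's camera adjusted p was 0.415, 0.000832 and 0.299, and without TA replicates 1, 2 and 3 it was 0.0169, 0.0893 and 0.315. For the cadherin list it was 0.223, 0.0257 and 0.299 without GS replicates 1, 2 and 3, and 0.0367, 0.0278 and 0.0268 without TA replicates 1, 2 and 3. Neither list was near the threshold with an estimated correlation (0.684 each).

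None of the 32 voltage-gated sodium, potassium and HCN channel genes tested was called over all genes, and 3 passed when adjusted over the list alone (camera adjusted p of 0.517). Kcnip4, a potassium channel interacting protein, was at 19.9 ± 4.18 RPKM in GS and 4.49 ± 0.963 RPKM in TA, with a limma adjusted p of 0.0762. Kcnd3 and Kcnq3, potassium channel subunits, were at 4.47 ± 0.379 and 23.9 ± 6.83 RPKM in TA and 0.343 ± 0.307 and 7.19 ± 0.888 RPKM in GS. Of 22 GABA and glutamate receptor genes none was called (camera adjusted p of 0.243). Gabra5 was at 34.7 ± 4.07 RPKM in GS and 14.1 ± 3.12 RPKM in TA, and Grm3 at 10.8 ± 4.08 and 33.4 ± 12.6 RPKM.

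None of 13 neurotrophic factor receptors and ligands was called (camera adjusted p of 0.361), and Ret, a receptor tyrosine kinase, was at 3.28 ± 1.45 RPKM in TA and 0.768 ± 1.18 RPKM in GS. None of 9 targets of BMP, Wnt, retinoid and FGF signals was called (camera adjusted p of 0.473), and 1 passed towards GS when adjusted over the list alone, Id3, at 5.18 ± 2.45 RPKM in GS and 0.658 ± 0.482 RPKM in TA. None of 14 immediate early and nerve injury genes was called (camera adjusted p of 0.232, or 0.684 with an estimated correlation, and 0.0257 to 0.617 without 1 replicate), and Jun was at 30.6 ± 5.81 RPKM in GS and 14.7 ± 2.99 RPKM in TA. None of 24 cytosolic ribosomal protein genes (camera adjusted p of 0.960) and none of 30 nuclear genes of the mitochondrial respiratory chain (0.559) was called. No list passed camera over all 6 libraries, where 4 had an unadjusted p under 0.05, against 1 with an estimated correlation and 1 with the set test fry by direction. Fry in either direction, which asks whether members differ at all and not whether they differ more than other genes, passed 10 of 22 lists. These were the muscle-type (adjusted p of 0.000138), identity (0.00655), glial (0.0193), cadherin (0.00268), Eph (0.00268), semaphorin (7.45e-06), Slit and Robo (0.0351), channel (0.0245), GABA and glutamate receptor (0.0269) and BMP target lists (0.0193). Camera compares a list with all other genes, whose median lay towards TA, and 5 lists with a median and mean log2 fold change above 0 had GS as camera's direction, namely identity, Slit and Robo, channel, ribosomal and respiratory chain genes. In 3 lists, nociceptor, cadherin and BMP target genes, the median and the mean differed in sign.

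Of 15 identity genes tested, Spp1 was called, higher in GS, and the camera adjusted p was 0.583. Pvalb, which encodes parvalbumin, after which the reporter line is named, was singled out after its values were seen. It was at 69.0, 93.5 and 47.8 RPKM in TA replicates 1, 2 and 3 and at 4.26, 10.4 and 31.3 RPKM in GS replicates 1, 2 and 3, with a log2 fold change of 2.46 ± 0.58 and a limma adjusted p of 0.168 over all genes. Adjusted over the list alone, Pvalb passed as higher in TA and Spp1 as higher in GS.

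Summed over each list, identity genes came to between 7160 and 10178 RPKM per library and each list of markers of other cell types to at most 305 RPKM. Much of the identity sum came from Nefl and Nefm, at 4478 and 4585 RPKM in GS replicate 1 and 3787 and 2167 RPKM in GS replicate 3. The sum therefore does not measure how pure the pools were in proprioceptors. Skeletal muscle markers summed to 305 RPKM in TA replicate 3 and to between 0.233 and 5.12 RPKM in the other 5 libraries. Acta1 and Actc1, sarcomeric actins, were at 84.9 and 55.3 RPKM in TA replicate 3, and Myh3, embryonic myosin, at 43.2 RPKM. Acta1 reached at most 5.01 RPKM elsewhere, and Actc1 was listed at 0 in the other libraries. Connective tissue and vascular markers summed to 35.0 RPKM in TA replicate 3 and at most 6.29 RPKM elsewhere. Neither list passed camera over all libraries (adjusted p of 0.232 and 0.866), and the muscle list had 0.708 with an estimated correlation. Without TA replicates 1, 2 and 3 in turn the muscle list's camera adjusted p was 0.00140 and 0.00513 towards TA and 0.364 towards GS, and without GS replicates 1, 2 and 3 it was 0.415, 0.293 and 0.342 towards TA. Only Acta1 of this list passed the filter without TA replicate 3, so the value towards GS rests on 1 gene. Among the libraries kept, Acta1 was highest in GS replicate 2, at 5.01 RPKM. Smyd1 was at 31.1, 31.0 and 36.6 RPKM in TA replicates 1, 2 and 3.

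Nociceptor markers summed to between 35.0 and 192 RPKM, highest in GS replicate 2. Calca, encoding the peptide CGRP, was at 50.2, 133 and 0 RPKM in GS replicates 1, 2 and 3 and at 55.5, 2.92 and 55.2 RPKM in TA replicates 1, 2 and 3. P2rx3, an ATP receptor, was at 16.3 ± 6.94 RPKM in GS and 4.04 ± 0.849 RPKM in TA, with a limma adjusted p of 0.205, and passed when adjusted over the list alone. Glial markers summed to between 129 and 243 RPKM. Mechanoreceptor, red blood cell and immune, motor neuron and sex-linked lists held no called gene, and none of their members passed when adjusted over the list alone. The camera adjusted p was 0.361 for the 9 nociceptor genes tested, 0.243 for 10 glial genes and 0.517 for 3 mechanoreceptor genes. For 4 red blood cell and immune genes it was 0.443, and for 3 sex-linked genes 0.361. For the motor neuron list it was 0.361 and rests on 1 gene, Isl2. Xist, expressed from the inactive X chromosome, was at 6.54 ± 2.28 RPKM in TA and 7.59 ± 7.69 RPKM in GS, and the Y-linked Ddx3y at 3.40 ± 1.26 and 4.45 ± 1.62 RPKM.

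**Figure D3:**
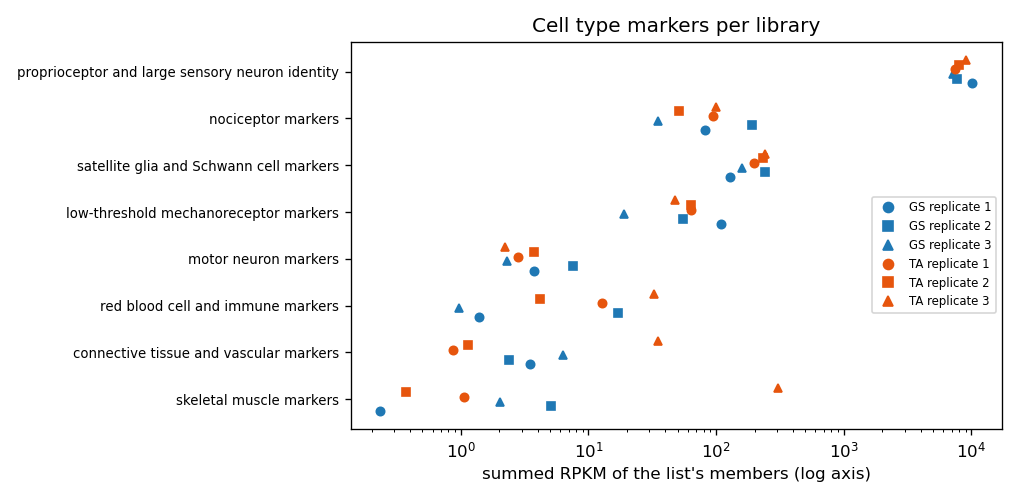
Summed RPKM of the members of 8 marker lists (log axis) in each library, with colour for muscle and symbol for replicate. The skeletal muscle sum is 305 RPKM in TA replicate 3 and at most 5.12 RPKM in the other 5 libraries.

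The second comparison set the deposited lists of genes higher in 1 muscle beside the replicate libraries. The authors' deposited table of genes higher in TA held 395 genes and that of genes higher in GS held 334, of which 52 and 64 had a deposited adjusted p under 0.05. The gene with the smallest deposited p in the authors' deposited table for TA was Myh3, with an adjusted p of 1.64e-20, and 99.7% of its TA RPKM lay in TA replicate 3. Ext2, an enzyme of heparan sulfate synthesis, had the smallest p in the authors' deposited table for GS, an adjusted p of 1.44e-18, with 95.4% of its GS RPKM in GS replicate 3. Alcam followed in the authors' deposited table for GS, with an adjusted p of 2.78e-10, and 41.1% in its highest library.

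In the TA list, 120 of 394 matched genes (30.5%) had at least 90% of their summed TA RPKM in 1 library, and in 111 of these it was TA replicate 3. In the GS list, 131 of 334 genes (39.2%) did, and in 98 of these it was GS replicate 2. TA and GS values did not overlap in the listed direction for 232 genes of the TA list (58.9%) and 107 of the GS list (32.0%). The listed genes were selected on these same libraries, so no chance level applies to these shares. Genes that passed the filter, 178 of the TA list and 232 of the GS list, all had the listed sign in the limma fit, which used the same libraries. Past the limma threshold were 18 genes of the TA list, of 19 called, and 14 of the GS list, of 14 called. The lists rest on the same samples, so this overlap compares methods and is not independent evidence.

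**Figure D4:**
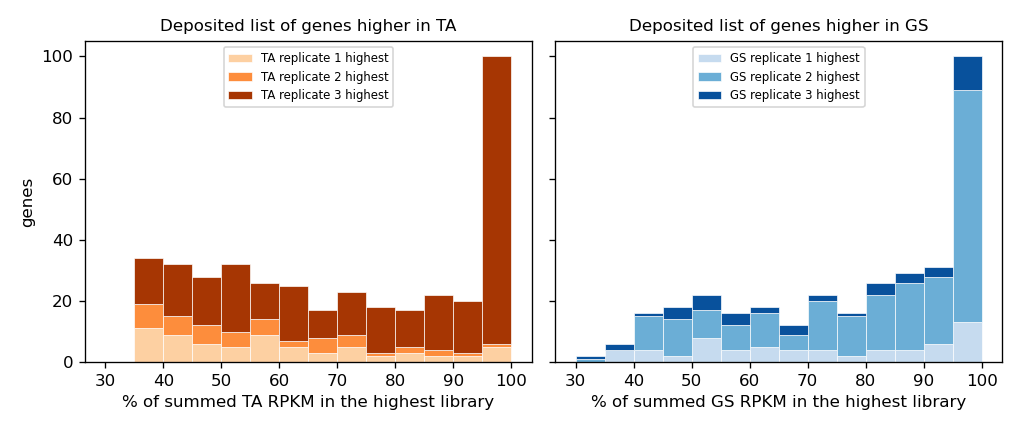
Number of genes in each deposited list by the percent of the summed RPKM of that muscle's 3 libraries found in the highest library, shaded by which replicate is highest. At 90% or more stand 120 TA list genes and 131 GS list genes.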

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

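All 33 called genes kept their direction wherever they were tested, and 27 of them entered the test at a mean RPKM of at least 5. The counts were less stable, and the cause was not tested. In some settings fewer libraries or other numbers of genes entered. With limma voom on net reads, an alternative chosen after seeing the data, 7 genes were higher in TA and 5 in GS, and 10 of these 12 were among the 33. Setting values below 0 to 0, also added, gave 19 and 14. A pseudocount of 0.1 gave 7 and 6, and a pseudocount of 5 gave 14 and 8. With no filter 18604 genes entered and limma called 0 and 0, with 1251 and 250 at an unadjusted p under 0.05. At a mean RPKM of at least 5 there were 9 and 8. Median centring gave 11 and 17, sample weights 44 and 25, and an adjusted p under 0.1 gave 35 and 20. Leaving out 1 replicate gave 1 to 19 genes higher in TA and 1 to 10 higher in GS. Leaving out GS replicate 2 and TA replicate 3 together, added later, gave 1 and 0, with 721 and 201 at an unadjusted p under 0.05. Vstm2b and Alcam were called in each fit without 1 replicate, and Vstm2b was the gene called with both libraries left out.

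Whether shared replicate numbers pair the samples is not given in the sources used here. Deviations from the muscle mean of same-numbered libraries correlated at -0.0744, -0.0185 and -0.135. Those of differently numbered libraries lay between -0.0378 and 0.132. The 3 deviations within a muscle sum to 0 for each gene, so these values cannot decide on pairing. With the replicate block 8 genes were higher in TA and 8 in GS.

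Of the deposited TA and GS lists, 18 and 14 genes passed the threshold, against 7 and 6 with a pseudocount of 0.1, 8 of the GS list with a pseudocount of 5, 0 and 0 with no filter, 8 and 8 at a mean RPKM of at least 5, 11 of the TA list with median centring, 8 and 8 with the replicate block, 31 and 23 with sample weights, 5 and 5 with voom, and 1 and 0 without both libraries. Leaving out 1 replicate gave 1 to 16 and 1 to 10. Mean correlations within TA, within GS and between muscles were 0.825, 0.677 and 0.712 with a pseudocount of 0.1, and 0.827, 0.692 and 0.726 by Spearman. With a pseudocount of 5 they were 0.912 within TA and 0.820 within GS, and at a mean RPKM of at least 5 they were 0.704 within GS.

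Leaving out 1 replicate put 0 to 3 lists past the threshold, and leaving out both libraries put 3 past it. These 3 were connective tissue, cadherin and Hox genes, all towards GS, with camera adjusted p of 0.0108, 0.0138 and 0.0108. Only Dcn of the connective tissue list passed the filter without both libraries, so that list's value rests on 1 gene. Some lists changed direction, at these adjusted p. With a pseudocount of 0.1 these were connective tissue and Eph genes (0.982 each), and with a pseudocount of 5 ribosomal protein genes (0.983). With no filter they were motor neuron (0.920) and ribosomal genes (0.826), at a mean RPKM of at least 5 mechanoreceptor and Eph genes (0.968 each), and with quantile normalization ribosomal genes (0.991). Under fry, which tests a list against 0 and not against other genes, they were identity (0.851), Slit and Robo (0.857), channel and ribosomal (0.529 each) and respiratory chain genes (0.666). Without both libraries they were nociceptor (0.973), connective tissue (0.0108, towards GS, on Dcn alone), Eph (0.834) and Slit and Robo genes (0.834). Over all 6 libraries the connective tissue list had a camera adjusted p of 0.947 with an estimated correlation. Adjusted p without 1 replicate ranged from 0.585 to 0.992 for Eph, 0.703 to 0.933 for ribosomal, 0.321 to 0.908 for respiratory chain, 0.200 to 0.950 for nociceptor, 0.304 to 0.933 for connective tissue, 0.415 to 0.919 for Slit and Robo, 0.299 to 0.919 for BMP, Wnt, retinoid and FGF target and 0.00140 to 0.415 for muscle genes.

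None of the 20 called genes named by the rule reversed, and 2 of them kept their call without each replicate. Some uncalled genes changed sign. Log2 values with quantile normalization were -0.25 for Nefm, -0.012 for Maf, -0.22 for Col1a2 and -0.010 for Xist. With median centring they were -0.17 for Nefl, -0.21 for Nefm, -0.13 for Col1a2 and -0.076 for Xist. With sample weights they were -0.013 for Nefm and -0.13 for Col1a2, and with voom -0.075 for Nefl, -0.091 for Nefm and -0.13 for Col1a2. Col1a2 was at -0.24 with a pseudocount of 0.1, and Calca at -0.13 and Dcn at 0.025 with a pseudocount of 5. Without both libraries Nefm was at -0.34, Apoe at 0.083 and Isl2 at 0.0061. Without 1 replicate the ranges were -0.013 to 0.94 for Efna5, -0.11 to 0.021 for Nefh, -0.11 to 0.55 for Maf, -0.26 to 0.60 for Col1a2, -0.33 to 0.83 for Xist, -0.28 to 0.41 for Nefm, -1.57 to 0.43 for Hbb-b2, -0.053 to 0.10 for Nefl, -1.83 to 1.70 for Calca, -0.48 to 0.83 for Gfra2, -1.44 to 0.31 for Dcn, -0.82 to 0.073 for Fabp7 and -1.13 to 1.98 for Acta1.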

Other observations

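The tests of explanations in this part were all chosen after the results they weigh were seen. A further 12 called genes, 11 of them matched to the reference name table, fell outside the rule for named genes, 8 higher in TA and 4 higher in GS, and were named after their values were seen. The homeodomain factors Meis2 and Zfhx3 were at 8.77 ± 0.777 and 16.0 ± 1.05 RPKM in TA and 0.720 ± 0.209 and 2.44 ± 0.753 RPKM in GS (SD, n = 3), with limma adjusted p of 0.0384 and 0.0385. Tacr3, the neurokinin 3 receptor, was at 6.33 ± 2.27 RPKM in TA and 0.0106 ± 0.0184 RPKM in GS (adjusted p of 0.0388). The glycan-modifying enzymes St6galnac5 and Hs6st1 were at 16.3 ± 2.06 and 15.4 ± 0.786 RPKM in TA and at 1.96 ± 0.553 and 1.86 ± 1.21 RPKM in GS. Dgkk, Khdrbs2 and Arhgap36 were also higher in TA. Higher in GS were Rspo2, an activator of Wnt signalling, at 9.23 ± 2.85 against 0.749 ± 0.214 RPKM, Prss12, a secreted protease, at 26.0 ± 3.72 against 5.69 ± 0.856 RPKM, and Dbc1, now named Brinp1, at 6.47 ± 0.0362 against 0.224 ± 0.249 RPKM. An entry named Ebf1 was at 28.4 ± 7.03 against 3.92 ± 1.93 RPKM, but its identifier did not match the reference name table and it spans only 44430819 to 44431275 of chromosome 11 (mm9).

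Of 22 genes with an adjusted p between 0.05 and 0.1, 5 were picked after their values were seen, and no gene group was tested among them. Odz1, a teneurin now named Tenm1, was at 33.9 ± 4.79 RPKM in TA and 7.49 ± 3.31 RPKM in GS (limma adjusted p of 0.0619). Ncam2, a cell adhesion molecule, was at 20.6 ± 9.44 RPKM in GS and 3.11 ± 0.865 RPKM in TA (adjusted p of 0.0619). Sema3d, a secreted semaphorin, was at 16.9 ± 1.84 RPKM in TA and 3.98 ± 0.797 RPKM in GS, and Pcdh17, a protocadherin, at 1.64 ± 1.86 and 16.6 ± 8.16 RPKM (both adjusted p of 0.0830). Kcnk9, a background potassium channel, was at 15.6 ± 4.78 RPKM in TA and 2.07 ± 1.87 RPKM in GS (adjusted p of 0.0797).

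The real split of the 6 libraries gave 33 called genes, and 1 of 10 splits, the real one, gave as many, with 0 in the highest of the others. With 10 splits the share cannot fall under 0.05, so this count alone does not decide on chance.

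Skeletal muscle transcripts stood out in TA replicate 3. Deeper sequencing of that library is argued against, since at 1 common depth its muscle marker reads were 96.0 times those of the next library. Expression of these 11 markers by TA proprioceptors in general is also argued against, since the median log2 difference of TA replicates 1 and 2 from GS was 0 (SD over the markers 0.47). This does not extend to every muscle gene, since Smyd1 was at 31.1, 31.0 and 36.6 RPKM in TA replicates 1, 2 and 3 and 1.72 ± 2.23 RPKM in GS. Muscle RNA or cells in that pool stay open under a cut-off set after the values were seen. Of 16 further muscle genes outside the fixed list, 8 were at 10 times or more the highest other library. The cut-off asked for more than 8. Apart from Tnni1, the genes that missed it (Ryr1, Cacna1s, Actn2, Actn3, Eno3, Pgam2 and Tcap) were also highest in TA replicate 3. Pgam2 was at 9.06 RPKM there and at most 1.48 RPKM elsewhere, and Cacna1s at 0.481 and at most 0.200 RPKM. Of the 11 fixed markers, which define the pattern, 10 were at 10 times or more the next library. Tnni1 was lower in TA replicate 3 (5.06 RPKM) than in the other 5 libraries (7.03 to 23.8 RPKM). It was thus present without raised muscle markers, so its level does not count against muscle RNA in that pool.

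GS replicate 2 stood apart from the other 5 libraries. Shallow sequencing is argued against, since its net read total ranked 5 of 6 from the lowest. A candidate explanation is that fewer RNA species were amplified in that pool, since at 1 common depth it held 1432 fewer detected features than the lowest other library, where the SD of the other 5 was 789. Low detection was not particular to it. At that depth GS replicates 1, 2 and 3 held 13775, 12343 and 15156 features, and TA replicates 1, 2 and 3 held 15898, 15389 and 15215. Each GS library held fewer than each TA library, so detection was confounded with muscle. RNA of another cell type stays open: 2 of the 6 marker lists reached 3 times the median of the others, red blood cell and immune at 16.9 RPKM and skeletal muscle at 5.12 RPKM, but TA replicate 3 exceeded both. Nociceptor and motor neuron markers were at 2.33 and 2.69 times that median, glial markers at 1.23 and connective tissue markers at 0.681. The nociceptor sum, 192 RPKM, and the motor neuron sum, 7.54 RPKM, were the highest of the 6 libraries. A difference between the animals pooled was not tested.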
